A study of Arabidopsis thaliana with 24 samples.

How the data were processed

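Total RNA from the aerial parts of 3-week-old Arabidopsis thaliana plants was measured on Affymetrix ATH1 GeneChips, which carry short oligonucleotide probes grouped into probe sets. Per the labels' protocols, the plants grew on agar medium with 1% sucrose at 22 °C under 16 h of light and 8 h of dark, and the RNA was labelled with biotin. The growth protocol, the same for all 24 arrays, also describes a drought experiment at 21 °C and 40% humidity. No label ties an array to it, so all were taken as untreated, which the labels do not state. The labels put the 24 arrays into 8 genotypes of 3 arrays each. They do not say whether the arrays of a genotype came from separate plants, pools or plates, so p-values measure the spread between these arrays, which may in part be technical.

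The deposited values are linear signal intensities, made by the authors with MAS5 per the submitters' processing notes. The version of that software, the definition of the probe sets and the harvest and hybridization dates are not given in the sources used here. The values themselves show the scaling: after trimming 2% at each end, the mean signal of the whole table was 500.0 on each of the 24 arrays. Such a scaling removes differences in overall brightness between arrays and would hide a shift of most genes in 1 direction. The table holds 1 signal per probe set and no detection call, so a low signal cannot be told from background here. Median signals ranged from 163.9 to 176.7 per array. The percentage of probe sets above 85.2 ranged from 59.5% to 62.2%. No 2 arrays shared a signal in any probe set, and the mean correlation of an array with the other arrays of its genotype lay between 0.980 and 0.992 across probe sets. The number of arrays per genotype limits the precision.

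The table lists 22810 probe sets, of which 64 are control probe sets and were left out of the tests. An offset of 42.6, the overall median signal of 170.4 divided by 4, was added to each signal before taking log2. The offset damps noise at low signals and understates the fold change of dim probe sets. Probe sets above a signal of 85.2, the overall median divided by 2, on at least 3 of the 24 arrays were tested, which kept 14935 of 22746. All 8 genotypes entered 1 linear model with 1 mean per genotype, leaving 16 residual degrees of freedom, and 13 contrasts were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend). P-values were adjusted by the Benjamini-Hochberg method over the probe sets of each contrast, and an adjusted p under 0.05 counted as changed. All adjusted p-values below come from these limma fits unless another test is named. Of the 13 contrasts, 10 compare a pair of genotypes and 3 are interactions, which compare the effect of a genotype between backgrounds.

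Gene names came from a table that pairs the probe sets with the platform annotation, updated through the Entrez identifiers of the RefSeq gene table of assembly TAIR10.1, which was used for names only. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 had no gene name in that table. Among those with 1 gene, 13436 matched the RefSeq table. Probe sets with several genes or none were tested but not named, apart from a few unnamed probe sets that are described by their signals because these followed the genotypes, a choice made after their values were seen. Genes named with an AT code carry no other symbol in the RefSeq table. The build behind the array's design is not given in the sources used here, so no coordinates are printed.

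The tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes every tested member of 22 gene lists and, outside the lists, up to 6 genes with the largest rise and up to 6 with the largest fall per pair of genotypes. These had to be changed, to have a mean signal above 85.2 in the brighter genotype and to have arrays of both genotypes that do not overlap. For interactions it takes up to 4 in each direction. A gene with several probe sets is represented by the one with the highest mean. The lists held 236 genes, but only 28 of them had a probe set with 1 gene name and 25 were tested. That left 13 lists with a tested member, of which 3 had at least 3 members and were tested as sets: the anthocyanin branch, flavonol glycosylation, and auxin transport and response. The other 10 covered the flavonoid core pathway, lignin and sinapate, the shikimate pathway, aliphatic and indole glucosinolates, jasmonate, drought and abscisic acid, oxidative stress, photosynthesis and the circadian clock. The 9 lists without a tested member included the flavonoid regulators and the marker lists of root, seed and flower. The genes behind the studied alleles, MYB12, PAP1 and CHS, are not named in the annotation used here, so the check of the target genes by name was not analysed here.

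Gene sets were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a set move on balance in 1 direction. Because so few list members were named, families of at least 5 tested genes that share a symbol stem, plus the tested genes of the plastid chromosome, were added after the data had been seen, giving 35 sets. A list of 16 anther markers was also added, of which 4 were tested.

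The labels number the arrays of each genotype from 1 to 3 without saying that a number marks a shared batch. Whether same-numbered arrays deviate together from their genotype means was therefore tested by correlation across probe sets. For 3 of the 10 pairs of genotypes every number gave a correlation over 0.1: pap1-D/tt4 and pap1-D (lowest 0.125), MYB12OX/tt4 and tt4 (lowest 0.112), and WOX1-2 and WOX1-1 (lowest 0.142). For these pairs the value with the replicate number as a block is given where it moves a count by more than 1.5 times. Other alternatives were the offset, the filter, quantile normalization, the variance trend, array weights, a fit on the contrasted genotypes alone and the omission of each array in turn. Added after seeing the data were a fit with the place of the array in the sample listing as a covariate and a fit without the arrays numbered 1.

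The tests were also run on simulated data with 200 probe sets changed, made from the mean and residual spread of each of the 14935 probe sets. The noise was independent between probe sets, and no other genotype difference and no change along the listing was put in. For the comparison of tt4 with Col-0, 65.1% of the 63 probe sets changed 1.5-fold were recovered, 93.0% of the 71 changed 2-fold and 100% of the 66 changed 4-fold, with 8 false calls among 181. For the pap1-D by tt4 interaction the shares were 42.9%, 84.5% and 100%, with 9 false calls among 162. A simulated set of 5 genes lowered by 0.7 on the log2 scale was called with both correlations, and 0 of the other sets were. The simulated genes were not correlated, while the correlation estimated in the 3 real lists ran from 0.22 to 0.48. The simulation therefore does not test calls of real lists at the preset correlation. Figures were drawn with matplotlib 3.10.9.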

Results

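The series compares Arabidopsis plants that overaccumulate flavonoids with plants that lack them. Flavonoids are plant phenolics that include the pale flavonols and the red to purple anthocyanins. MYB12OX overexpresses MYB12, a regulator of flavonol synthesis. The line pap1-D overexpresses PAP1, a regulator of anthocyanin synthesis. WOX1-1 and WOX1-2 are 2 lines from the cross of MYB12OX with pap1-D. The mutant tt4 lacks chalcone synthase (CHS), the first enzyme of the flavonoid pathway, and MYB12OX/tt4 and pap1-D/tt4 carry an overexpressed regulator without that enzyme. With the wild type Col-0 this gives 8 genotypes, each with 3 ATH1 arrays of RNA from aerial parts. The levels below are MAS5 signals, and changes are differences of log2(signal + 42.6) with their SE from the common limma fit.

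The signals of 2 probe sets without a gene name followed the labels on all 24 arrays. The MYB12OX-linked probe set averaged 2367 ± 126 (SD, n = 3) in MYB12OX against 45.6 ± 6.43 (SD, n = 3) in Col-0. Its mean was 2262 in WOX1-1, 2252 in WOX1-2 and 2423 in MYB12OX/tt4, but 29.1 in pap1-D, 19.8 in pap1-D/tt4 and 27.1 in tt4. The pap1-D-linked probe set averaged 4924 ± 146 (SD, n = 3) in pap1-D against 53.0 ± 15.3 (SD, n = 3) in Col-0. Its mean was 4123 in WOX1-1, 3663 in WOX1-2 and 3537 in pap1-D/tt4, but 40.0 in MYB12OX, 20.7 in MYB12OX/tt4 and 14.3 in tt4. A further unnamed probe set averaged 1409 ± 59.1 (SD, n = 3) in pap1-D, 198 ± 38.5 (SD, n = 3) in Col-0 and 107 ± 8.33 (SD, n = 3) in pap1-D/tt4. These probe sets were chosen after their values were seen, and the annotation used here gives no gene for them.

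**Figure D1:**
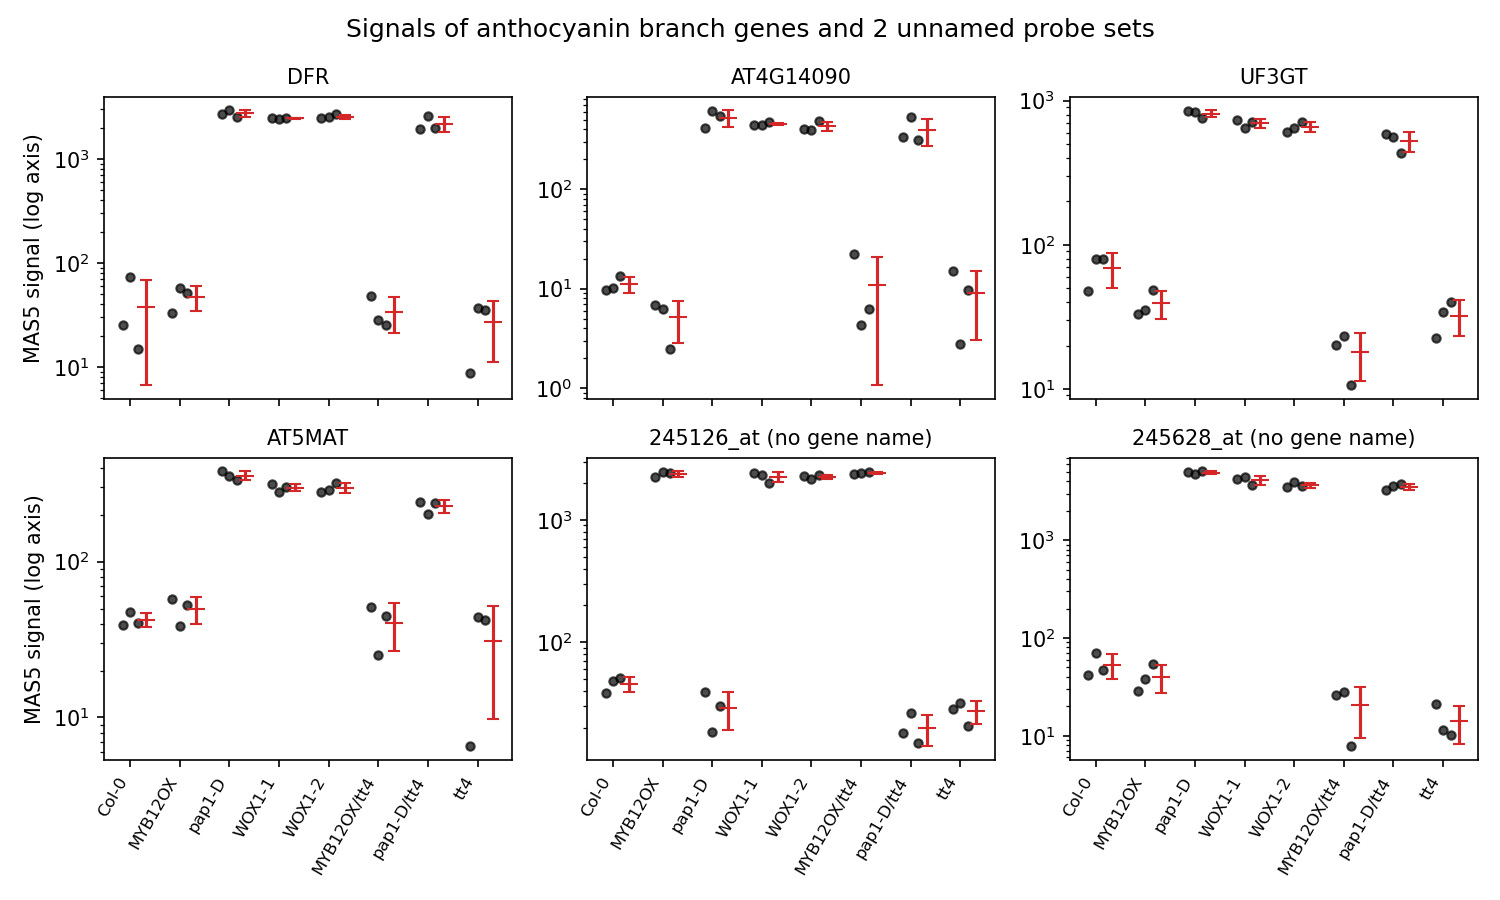
MAS5 signals on a log axis for DFR, AT4G14090, UF3GT and AT5MAT, genes of the anthocyanin branch, and for the MYB12OX-linked and pap1-D-linked unnamed probe sets, by genotype; black points are arrays, red dashes and bars are the mean and SD of 3 arrays. DFR averaged 2728 in pap1-D and 2159 in pap1-D/tt4, against 38.0 in Col-0 and 27.1 in tt4.

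The comparison of pap1-D with Col-0 asked which genes an overexpressed anthocyanin regulator changes. All 4 tested genes of the anthocyanin branch rose. DFR (dihydroflavonol reductase), which commits flavonoids to anthocyanins, rose by 5.17 ± 0.19 (SE) on the log2 scale, from a signal of 38.0 ± 31.3 to 2728 ± 192 (SD, n = 3 each). The glucosyltransferase gene AT4G14090 rose by 3.37 ± 0.16, the xylosyltransferase gene UF3GT by 2.95 ± 0.13 and the malonyltransferase gene AT5MAT by 2.23 ± 0.16. The 4 genes also passed when adjusted over the list alone, and the list was called by camera (adjusted p = 2.28e-21; adjusted p = 3.33e-06 with an estimated correlation). Of 3 flavonol glycosylation genes, UGT78D2, which glucosylates flavonols and anthocyanins alike, rose by 0.79 ± 0.14, and the flavonol rhamnosyltransferase gene AT1G06000 fell by 0.80 ± 0.17. For UGT78D1 the difference was -0.46 ± 0.18 (adjusted p = 0.114), which passed when adjusted over the list alone. HCT, an enzyme of lignin synthesis, fell by 0.29 ± 0.07.

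Outside the lists, the largest rises in pap1-D were those of AT1G09500, related to cinnamyl alcohol dehydrogenases (2.30 ± 0.29), AT2G27080 (2.30 ± 0.69) and AT1G50040 (1.72 ± 0.27). AT2G27080 read 2541 on pap1-D replicate 1 and 211 and 364 on the other arrays of that line, and without that array its difference was 1.3 (adjusted p = 0.218). The array stood apart from them on the second principal component (-22.3 against -5.58 and -8.57). EXO, a growth gene induced by brassinosteroids, rose by 1.64 ± 0.20, AT5G25440 by 1.55 ± 0.20 and AT3G59350 by 1.53 ± 0.14. The largest falls were those of AT1G72920 (-1.63 ± 0.26), AT1G20070 (-1.42 ± 0.18) and ROXY2, a glutaredoxin gene of anther development (-1.33 ± 0.25). ROXY2 averaged 124 ± 33.8 in Col-0 and only 23.8 ± 14.9 in pap1-D (SD, n = 3 each). Its fall did not pass in WOX1-1 (-0.10, adjusted p = 0.842) or WOX1-2 (-0.43, adjusted p = 0.235) against Col-0. AT5G01790, AT5G22430 and the cytochrome P450 gene CYP71B26 changed by -1.12 ± 0.11, -1.12 ± 0.27 and -1.09 ± 0.11. In all, 757 probe sets were higher and 751 lower in pap1-D, of 14935 tested, and 72 of them differed at least 2-fold. Without Col-0 replicate 1 the fit called 716 probe sets, without pap1-D replicate 3 it called 879, without the arrays numbered 1 it called 992, and on these 2 genotypes alone 935. With the place of the array in the listing as a covariate, 163 were called, and the 4 anthocyanin genes still passed.

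In MYB12OX against Col-0 the tested pathway genes did not pass. Of the 6 genes in the flavonoid core list only 1, CHIL, was tested. The others, among them CHS, had no probe set with 1 gene name. This comparison therefore does not show whether the flavonol pathway as a whole changed. The differences were 0.21 for DFR, 0.11 for AT5MAT, -0.17 for AT4G14090 and -0.44 for UF3GT, and 1 of the 4, that of UF3GT, passed when adjusted over the list alone. The chalcone isomerase-like gene CHIL was at 0.51 ± 0.31 (adjusted p = 0.548), UGT78D1 at -0.36, UGT78D2 at -0.23 and AT1G06000 at -0.15. Outside the lists, EXO rose by 1.27 ± 0.20 and the expansin-like gene EXLA1 by 0.90 ± 0.16. AT1G50040 rose by 1.62 ± 0.27, AT3G19680 by 1.07 ± 0.23, AT1G77640 by 1.06 ± 0.25 and AT5G25440 by 0.97 ± 0.20. The falls were led by AT2G20870 (-2.0 ± 0.31), AT5G22430 (-1.60 ± 0.27) and AT5G62210 (-1.48 ± 0.32). RXF26, AT1G78170 and AT4G19430 changed by -1.28 ± 0.27, -0.84 ± 0.14 and -0.83 ± 0.14. All comparisons with Col-0 share its arrays, so a deviation of these arrays would recur in each of them. AT1G50040 averaged 198 ± 128 (SD) in Col-0, 651 in MYB12OX and 439 in tt4, and AT5G62210 averaged 114, 13.6 and 31.9. Not all genes did so, as AT2G20870 averaged 1091 in Col-0, 247 in MYB12OX and 901 in tt4. Altogether 84 probe sets were higher and 66 lower, and 18 differed at least 2-fold. Without Col-0 replicate 1, AT1G77640 was at 0.70 (adjusted p = 0.269) and AT5G25440 at 0.60 (adjusted p = 0.122). The count was 34 without Col-0 replicate 1, 69 without MYB12OX replicate 2, 40 without MYB12OX replicate 3, 82 on the 2 genotypes alone, 338 with the replicate number as a block, 353 with array weights and 24 with the listing place as a covariate.

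The anthocyanin branch rose in both lines that carry MYB12OX and pap1-D together. Against Col-0, 4 of 4 anthocyanin branch genes rose in WOX1-1 and 4 of 4 in WOX1-2, also when adjusted over the list alone. DFR rose by 5.01 ± 0.19 and 5.07 ± 0.19, UF3GT by 2.74 ± 0.13 and 2.66 ± 0.13. Camera called the list in both lines, with adjusted p = 2.4e-05 and 9.77e-05 with an estimated correlation. UGT78D2 rose by 0.58 ± 0.14 in WOX1-1 and 0.50 ± 0.14 in WOX1-2, while UGT78D1 fell by 0.68 ± 0.18 and 0.87 ± 0.18 and AT1G06000 by 0.91 ± 0.17 and 0.67 ± 0.17. CHIL rose by 0.91 ± 0.31 in WOX1-1 and was at 0.77 ± 0.31 in WOX1-2 (adjusted p = 0.0837). HCT fell in both lines, by 0.39 ± 0.07 and 0.56 ± 0.07, and so did AT2G31790, a glucosyltransferase gene of glucosinolate synthesis, by 0.57 ± 0.15 and 0.82 ± 0.15. BCAT4, at the entry to methionine-derived glucosinolates, fell by 0.72 ± 0.18 in WOX1-1 and was at -0.39 ± 0.18 in WOX1-2. The glucosinolate gene UGT74B1 fell by 0.47 and the shikimate pathway gene AT1G22410 by 0.35 in WOX1-2, where the sinapate gene ALDH2C4 rose by 0.20 and the cold and drought gene COR47 by 0.69.

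The largest rises outside the lists included AT2G27080 (2.26 ± 0.69 in WOX1-1 and 2.22 ± 0.69 in WOX1-2), AT1G09500 (2.1 ± 0.29 and 2.13 ± 0.29), AT3G59350 (1.98 ± 0.14 and 2.05 ± 0.14) and EXLA1 (1.76 ± 0.16 in both). AT2G27080 read 2514 on WOX1-1 replicate 1, which lay at -22.1 on the second component against -7.81 and -7.61 for the other arrays of the line, and without it the difference was 1.25 (adjusted p = 0.193). EXO and AT1G50040 each rose by 2.03 in WOX1-1, and AT5G25440 by 2.04 and COR27, a cold-regulated gene tied to the circadian clock, by 1.90 in WOX1-2. The alpha-expansin gene EXPA8 fell by 1.60 ± 0.12 in WOX1-1 and 2.03 ± 0.12 in WOX1-2, CYP71B26 by 1.63 ± 0.11 and 1.77 ± 0.11, AT1G72920 by 1.86 ± 0.26 and 1.62 ± 0.26, and AT3G44450 by 1.44 ± 0.18 and 1.68 ± 0.18. AT1G20070 and the wall-associated kinase gene AT1G69730 were also among the largest falls in WOX1-1 (-1.48 and -1.40), and AT5G02230 and AT1G60590 in WOX1-2 (-1.65 and -1.61). WOX1-1 had 1147 probe sets higher and 1357 lower than Col-0, and WOX1-2 had 1642 higher and 1804 lower. Without Col-0 replicate 1 the WOX1-1 count was 1597, and with the listing place as a covariate the counts were 139 and 103. In that fit 4 of the 23 named genes of WOX1-1 had the other sign (AT1G50040, AT3G44450, BCAT4 and AT2G31790), all with an adjusted p above 0.05. So did 8 of the 25 of WOX1-2: AT3G44450, AT1G72920, AT1G60590, ALDH2C4, AT1G06000, AT1G22410, AT2G31790 and UGT74B1. With the covariate AT5MAT was at 1.68 ± 0.48 in WOX1-1 (adjusted p = 0.0938) and 1.57 ± 0.62 in WOX1-2 (adjusted p = 0.236).

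A direct comparison of WOX1-2 with WOX1-1 called 0 probe sets in limma, with a smallest adjusted p of 0.129. At an unadjusted p under 0.05 there were 1242, where 747 would be expected by chance. DFR differed by 0.06 ± 0.19 between the lines (adjusted p = 0.964). With the replicate number as a block 12 probe sets were called, with array weights 11, with the listing place as a covariate 3 and without the arrays numbered 1 it was 2.

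The comparison of tt4 with Col-0 asked what changes in plants that make no flavonoids. Of 5 flavonol glycosylation genes, the 3 that were tested fell: AT1G06000 by 1.03 ± 0.17, UGT78D1 by 0.58 ± 0.18 and UGT78D2 by 0.46 ± 0.14. Camera called this list at its preset correlation (adjusted p = 0.0435), but not otherwise (adjusted p = 0.203 with an estimated correlation). All 3 genes passed when adjusted over the list alone. Of the anthocyanin genes, UF3GT fell by 0.57 ± 0.13 and the other 3 did not pass, DFR at -0.17 ± 0.19. Auxin-responsive genes rose, GH3.3 by 1.55 ± 0.31 and IAA29 by 0.90 ± 0.20, while WES1 was at 0.55; over the list alone all 3 passed. Camera gave the auxin list the same result, adjusted p = 0.0435 at the preset and adjusted p = 0.203 with an estimated correlation. The aliphatic glucosinolate genes BCAT4 and AT2G31790 fell by 1.14 ± 0.18 and 1.04 ± 0.15. HCT fell by 0.45 ± 0.07, the shikimate gene AT1G22410 by 0.31, the clock gene GI by 0.23 and RCA, the activase of Rubisco, by 0.23 ± 0.08. ALDH2C4 rose by 0.50 ± 0.07, and of 2 cold and drought genes COR47 rose by 0.69 and COR15A fell by 0.69. COR47 was at 0.41 without tt4 replicate 1 (adjusted p = 0.124) and UGT78D2 at -0.30 without tt4 replicate 2 (adjusted p = 0.0999).

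Outside the lists, the largest rises in tt4 were those of AT3G23550 (2.61 ± 0.36), COR27 (2.45 ± 0.15), the AP2/ERF factor gene AT1G64380 (2.24 ± 0.19), AT5G25440 (2.13 ± 0.20), AT1G72060 (1.98 ± 0.16) and AT3G59350 (1.86 ± 0.14). The largest falls were those of AT1G13650 (-2.93 ± 0.18), EXPA8 (-2.42 ± 0.12), AT5G02230 (-2.26 ± 0.17), AT1G73600 (-2.19 ± 0.14), AT1G60590 (-2.12 ± 0.22) and AT5G21100 (-1.80 ± 0.11). EXPA8 averaged 5455 ± 559 in Col-0 and 984 ± 131 in tt4 (SD, n = 3 each), and COR27 averaged 708 ± 167 and 4008 ± 412. In total 2873 probe sets were higher and 2576 lower in tt4. Without Col-0 replicate 1 the fit called 4499, the fewest of the fits that left out 1 array.

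The arrays also differed along the order in which the samples are listed, from Col-0 first to tt4 last. The first principal component, with 34.5% of the variance, had means of -25.4 in Col-0, -18.2 in MYB12OX, -10.7 in pap1-D, -3.75 in WOX1-1, 5.30 in WOX1-2, 12.6 in MYB12OX/tt4, 19.1 in pap1-D/tt4 and 21.1 in tt4. The array numbered 3 lay above the array numbered 1 on it in 8 of 8 genotypes. COR27 followed the same order, with means of 905, 1412, 1859, 2721, 3214 and 3693 in the 6 genotypes listed between Col-0 and tt4. EXPA8 followed it in the other direction up to pap1-D/tt4, with means of 3466, 2736, 1774, 1304, 1101 and 979, and was at 984 in tt4. Not all of the largest changes in tt4 ran this way. AT3G23550 averaged 291, 469, 386, 405 and 612 in listing order in the genotypes with CHS, and 1212, 1687 and 1980 in those without. AT3G59350 rose up to WOX1-1 (4944) and then stayed near that level, at 5139 in WOX1-2 and 4467 in tt4. With the listing place as a covariate, 84 probe sets were called between tt4 and Col-0. Of the 27 genes given above as changed in tt4, 18 had the other sign in that fit, all with an adjusted p above 0.05. These were COR27 (-0.20), AT5G25440 (-0.55), AT1G72060 (-1.33), AT1G73600 (1.03), AT1G60590 (2.47), AT1G06000 (0.26), UGT78D1 (0.76), UGT78D2 (0.057), GH3.3 (-3.24), IAA29 (-3.63), BCAT4 (1.38), AT2G31790 (1.29), HCT (0.31), AT1G22410 (0.75), GI (0.12), RCA (0.11), ALDH2C4 (-0.22) and COR15A (1.54). That fit estimates the trend only from differences between arrays of a genotype, so its errors grow with the distance in the listing.

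**Figure D2:**
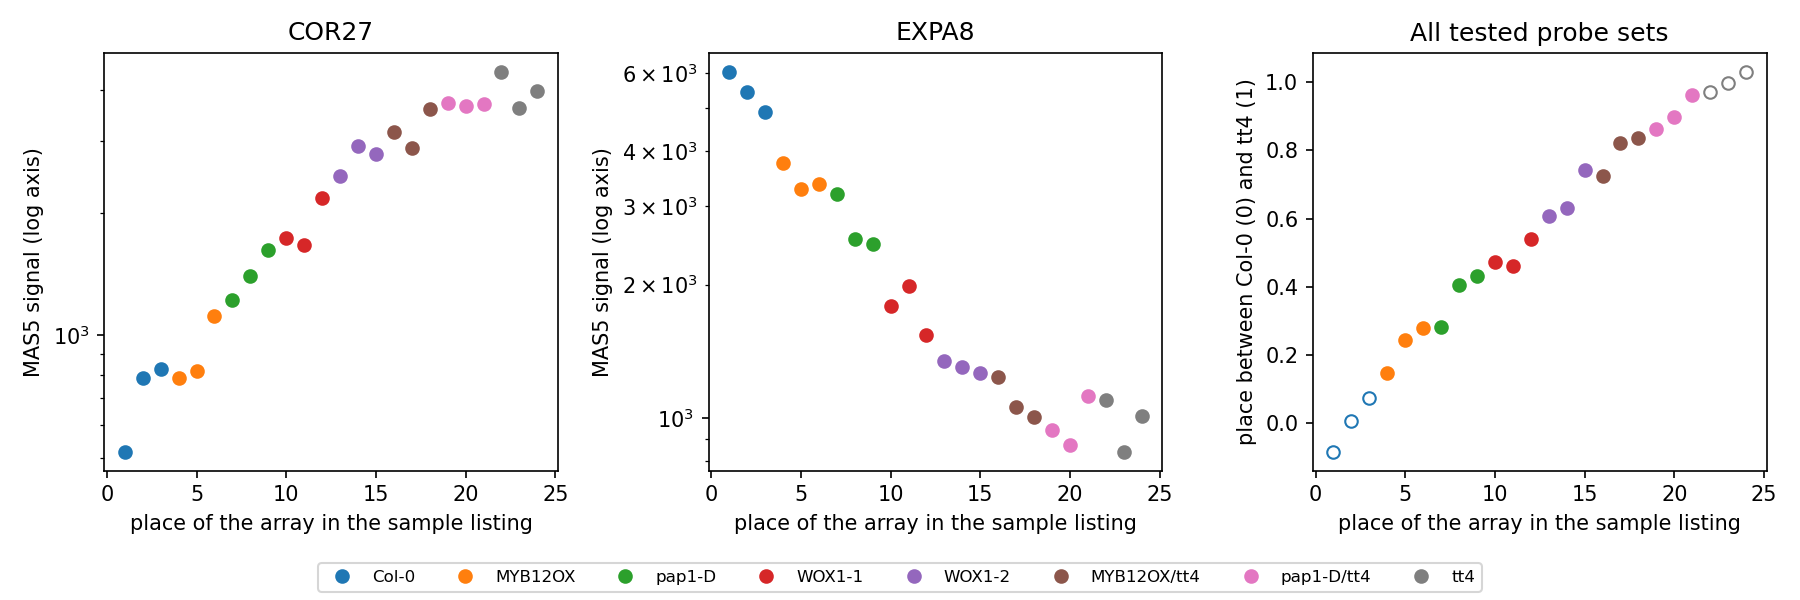
COR27 and EXPA8 signals (log axes) and the place of each array along the tt4 minus Col-0 difference over 14935 probe sets (Col-0 mean 0, tt4 mean 1), against the place of the array in the sample listing; each point is 1 array, coloured by genotype, and open circles mark the arrays that define the difference. WOX1-2, with intact CHS, averaged 0.66 and MYB12OX/tt4 0.79.

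Plants without CHS were also compared with plants with CHS where a regulator was overexpressed. In MYB12OX/tt4 against MYB12OX, the expansin genes EXPA8 and EXPB1 fell by 1.62 ± 0.12 and 1.41 ± 0.17. AT1G13650 fell by 2.30 ± 0.18, AT1G04770, a gene of the sulfur deficiency response, by 1.69 ± 0.11, AT5G21100 by 1.56 ± 0.11 and AT5G02230 by 1.45 ± 0.17. COR27 rose by 1.79 ± 0.15, AT1G64380 by 1.75 ± 0.19, AT1G66850 by 1.83 ± 0.44, AT2G20870 by 1.52 ± 0.31, AT1G68875 by 1.58 ± 0.54 and the anther gene ATA27 by 1.67 ± 0.51. Of the listed genes, BCAT4 (-0.63), AT2G31790 (-0.76), AT1G06000 (-0.71), UF3GT (-0.43), HCT (-0.34), AT1G22410 (-0.24), AT5G66120 (-0.20) and RCA (-0.23) fell, and GH3.3 (0.96), IAA29 (0.59) and ALDH2C4 (0.22) rose. The flavonol glycosylation list was called as lower at the preset correlation (adjusted p = 0.0454; adjusted p = 0.293 with an estimated correlation), with 1 of 3 genes passing over all probe sets and 3 of 3 when adjusted over the list alone. In total 1374 probe sets were higher and 1229 lower. The fit called 1609 without MYB12OX replicate 1, 1571 without MYB12OX/tt4 replicate 3 and 45 with the listing place as a covariate. With that covariate 8 of the 23 genes named here had the other sign, all with an adjusted p above 0.05: GH3.3 (-1.77), IAA29 (-2.0), ALDH2C4 (-0.19), BCAT4 (0.81), AT2G31790 (0.58), AT1G06000 (0.023), HCT (0.10) and AT1G22410 (0.37).

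In pap1-D/tt4 against pap1-D, the defensin genes PDF1.2b and PDF1.2 rose by 2.84 ± 0.75 and 2.21, the glucanase gene AT4G16260 by 1.63 ± 0.48 and the jasmonate oxidase gene AT5G05600 by 1.55 ± 0.51. AT3G23550 rose by 2.21 ± 0.36, AT2G38240 by 1.55 ± 0.52 and AT1G64380 by 1.38 ± 0.19. The PDF1.2b probe set is of a kind that can also read near-identical copies, so its value is uncertain. AT1G13650 fell by 2.40 ± 0.18, EXPA8 by 1.44 ± 0.12, AT5G19240 by 1.43 ± 0.32, AT5G48490 by 1.39 ± 0.10, AT3G04640 by 1.39 ± 0.35 and ORA47, a jasmonate-inducible factor gene, by 1.38 ± 0.38. Of 4 anthocyanin genes, UF3GT and AT5MAT fell, by 0.60 ± 0.13 and 0.57 ± 0.16, DFR and AT4G14090 were at -0.34 and -0.39, and 3 of the 4 passed when adjusted over the list alone. The list was called as lower (adjusted p = 0.0111; adjusted p = 0.108 with an estimated correlation). CHIL fell by 1.07 ± 0.31, UGT78D2 by 0.57 ± 0.14, AT2G31790 by 0.60 and RCA by 0.23, while GH3.3 rose by 0.92 and ALDH2C4 by 0.26. Single arrays carried several of these values. Without pap1-D replicate 1, which stood apart on the second component, ORA47 was at -0.65 (adjusted p = 0.0959), AT3G04640 at -0.84 (adjusted p = 0.0731) and GH3.3 at 0.54 (adjusted p = 0.273). AT5G05600 was at 0.56 (adjusted p = 0.246) and AT2G38240 at 0.46 (adjusted p = 0.264) without pap1-D/tt4 replicate 1, and CHIL at -0.51 (adjusted p = 0.155) without pap1-D/tt4 replicate 3. PDF1.2b was at 1.86 (adjusted p = 0.0784) and PDF1.2 at 1.44 (adjusted p = 0.17) without pap1-D replicate 3. The comparison called 1503 probe sets higher and 1321 lower, but 1723 in all without pap1-D replicate 1, 1550 on the 2 genotypes alone and 136 with the listing place as a covariate, where 6 of the 21 genes had the other sign (AT5G19240, AT3G04640, ORA47, GH3.3, ALDH2C4 and AT2G31790, all with an adjusted p above 0.05).

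The regulators' effects were then measured against tt4, without a working flavonoid pathway. In pap1-D/tt4 all 4 anthocyanin genes rose: DFR by 5.00 ± 0.19, AT4G14090 by 3.05 ± 0.16, UF3GT by 2.92 ± 0.13 and AT5MAT by 1.91 ± 0.16. All 4 passed when adjusted over the list alone, and the list was called with an estimated correlation (adjusted p = 6.92e-09). UGT78D2 rose by 0.67 ± 0.14 (adjusted p = 0.043). With the replicate number as a block this call was lost, and 0 of 3 flavonol glycosylation genes passed. The flavonol glycosylation list was called as higher and the auxin list as lower at the preset correlation, but not with an estimated one (adjusted p = 0.0606 and 0.0727), and 0 of 3 auxin genes passed. The auxin result depended on the fit, as camera with the block and an estimated correlation gave adjusted p = 0.00542. The sugar transporter genes AT1G34580 and AT4G04750 rose by 0.71 ± 0.12 and 0.54 ± 0.11, and AT5G65685 fell by 0.99 ± 0.08. In total 20 probe sets were higher and 2 lower. Of these 22, 19 were also changed in pap1-D against Col-0, a comparison that shares no array with this one: 17 were higher in both and 2 lower in both, where independent lists would share 1.01 and 0.101. The count was 14 on the 2 genotypes alone and 80 with the listing place as a covariate, with 16 of the 22 among them.

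In MYB12OX/tt4 against tt4, AT3G29120 rose by 1.05 ± 0.16, AT5G48490, a lipid transfer protein gene, by 0.88 ± 0.10 and AT2G34620 by 0.79 ± 0.10. The AT3G29120 probe set is of a kind that can also read near-identical copies, so its value is uncertain. The methionine sulfoxide reductase gene MSRB5 rose by 0.58 ± 0.11, AT4G12980 by 0.50 ± 0.10 and AT4G16980 by 0.36 ± 0.06. The named genes that fell were AT4G38540 (-0.79 ± 0.16), the sphingolipid lyase gene DPL1 (-0.47 ± 0.09) and the pyruvate decarboxylase gene PDC2 (-0.43 ± 0.07). None of the 25 listed genes passed, DFR at 0.15 ± 0.19. There were 19 probe sets higher and 9 lower, and 97 with the replicate number as a block. Of the 28, 3 were also called in MYB12OX against Col-0, which shares no array with this comparison: 1 was higher in both and 2 lower in both, where independent lists would share 0.107 and 0.0398. The count was 18 without MYB12OX/tt4 replicate 1, 12 without its replicate 2, 18 without tt4 replicate 1 and 16 without tt4 replicate 3. It was 12 without the arrays numbered 1, 9 on the 2 genotypes alone and 103 with array weights. With the listing place as a covariate 144 were called, but only 3 of the 28 were among them.

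Interactions tested whether a regulator's effect differed between plants with and without CHS, or between single and combined lines. The anthocyanin genes gave no call: for DFR the difference of the pap1-D effects was -0.17 ± 0.27 (adjusted p = 0.842), and for the combined lines against the sum of both single effects -0.34 ± 0.25 (adjusted p = 0.794). Between pap1-D and tt4, 79 probe sets were higher and 96 lower than the sum of the single effects. EXO rose with pap1-D by 1.64 in plants with CHS, and its interaction with tt4 was -1.38 ± 0.29. AT5G25440 (-1.52 ± 0.29), AT3G59350 (-1.40 ± 0.20) and AT1G72060 (-1.29 ± 0.23) were lower too. ROXY2 (1.58 ± 0.35), AT1G20070 (1.39 ± 0.26), AT5G01790 (1.13 ± 0.16), AT1G06000 (1.08 ± 0.24) and AT5G02830 (1.02 ± 0.21) were higher. The ROXY2 value rests on the low signal in pap1-D, a fall that did not pass in WOX1-1 or WOX1-2. In the listing pap1-D lies at 6 positions from Col-0, but pap1-D/tt4 at -3 from tt4. A gene that rises along the listing would therefore also give a negative interaction, and a gene that falls a positive one. AT1G72060, for example, averaged 267 in Col-0, 844 in WOX1-2 and 1198 in tt4. Between MYB12OX and tt4, 26 were higher and 14 lower, led by CYP78A9 (0.92 ± 0.17) and AT1G72060 (-1.09 ± 0.23). In the combined lines, 12 probe sets were higher and 19 lower than the sum of the MYB12OX and pap1-D effects. AT1G68670 and AT1G25550, which encode related GARP transcription factors, were lower by -1.03 ± 0.16 and -0.83 ± 0.12, and AT1G04770 by -0.76 ± 0.15. AT2G20870 (2.03 ± 0.41) and AT5G22430 (1.80 ± 0.36), which fell in MYB12OX, were higher.

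The counts of the interactions depended on the fit, on single arrays and on the listing place. With the replicate number as a block they became 184 for MYB12OX with tt4, 391 for pap1-D with tt4 and 55 for the combined lines. The 40 of MYB12OX with tt4 became 9 without the variance trend, 11 without the filter, 21 without the offset, 63 with quantile normalization, 137 with array weights and 5 without the arrays numbered 1. The 175 of pap1-D with tt4 became 60 on the 4 genotypes alone. The 31 of the combined lines became 18 without the variance trend, 18 without the filter, 17 on their own genotypes alone, 67 with array weights and 52 without the arrays numbered 1. With the listing place as a covariate, 34 probe sets were called for MYB12OX with tt4, 0 of them among the 40, 20 for pap1-D with tt4, 1 of them among the 175, and 75 for the combined lines, 29 of them among the 31. AT1G72060 had the other sign in both interactions with tt4 (0.33 and 0.13). For pap1-D with tt4 the count of 175 became 53 without Col-0 replicate 1, 99 without Col-0 replicate 2, 107 and 78 without pap1-D replicates 2 and 3, 83 without pap1-D/tt4 replicate 2, and 101 and 114 without tt4 replicates 2 and 3. For MYB12OX with tt4 the count of 40 became 2, 12 and 86 without Col-0 replicates 1, 2 and 3, 5 and 3 without MYB12OX replicates 2 and 3, 6, 19 and 18 without MYB12OX/tt4 replicates 1, 2 and 3, and 20, 7 and 14 without tt4 replicates 1, 2 and 3. For the combined lines the count of 31 became 12 and 56 without Col-0 replicates 1 and 3, 20 and 14 without MYB12OX replicates 2 and 3, 19, 16 and 14 without pap1-D replicates 1, 2 and 3, 67 and 16 without WOX1-1 replicates 1 and 3, and 18 without WOX1-2 replicate 2.

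**Figure D3:**
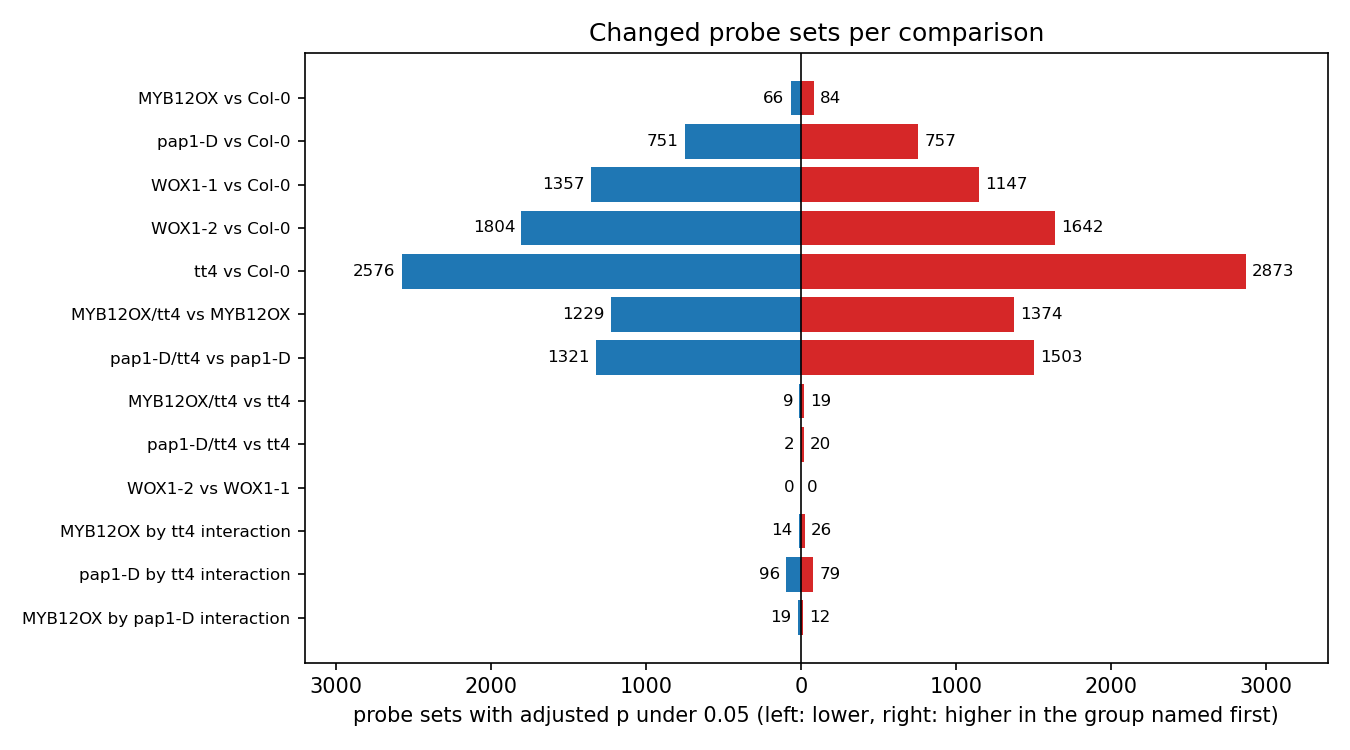
Number of probe sets with an adjusted p under 0.05 in each of the 13 comparisons, of 14935 tested, with those higher in the genotype named first to the right and those lower to the left; for interactions, right and left mean above and below the sum of the single effects. The bars run from 0 between WOX1-2 and WOX1-1 to 2873 higher and 2576 lower in tt4 against Col-0.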

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

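The within-genotype permutations of components 1 and 3, the shares carried along the listing, the CHS, RNA quality and signal ratio tests and the GSTU difference were chosen after the results had been seen; the splits, the step size, the anthocyanin fit with listing place and the GSTU permutation had written predictions first.

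A difference between backgrounds, tested by an interaction term, brought up each result here. For MYB12OX with and without CHS, 40 probe sets passed. Named were CYP78A9 (0.92), AT4G19430 (0.92), EXPA8 (0.80), AT1G70420 (0.79), AT1G72060 (-1.09), AT1G52200 (-0.81), AT2G30990 (-0.66) and AT2G46900 (-0.54). A probe set without a gene name, chosen after its values were seen, was at 2.53 and averaged 476 in Col-0, 46.5 in MYB12OX, 300 in tt4 and 328 in MYB12OX/tt4. For pap1-D with and without CHS, 175 passed. Named were ROXY2 (1.58), AT1G20070 (1.39), AT5G01790 (1.13), AT1G06000 (1.08), AT5G02830 (1.02), AT5G25440 (-1.52), AT3G59350 (-1.40), EXO (-1.38) and AT1G72060 (-1.29), and an unnamed probe set high in pap1-D, also chosen afterwards, was at -2.37. For the combined lines against the sum of MYB12OX and pap1-D, 31 passed. Named were AT2G20870 (2.03), AT5G22430 (1.80), AT1G78170 (1.05), AT1G79160 (1.01), AT1G68670 (-1.03), AT1G25550 (-0.83), AT1G04770 (-0.76) and AT3G59080 (-0.72).

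The same arrays were regrouped in other ways to see how many calls arise without the real grouping. Of 100 splits, 12 gave at least the 40 calls of MYB12OX with tt4 (highest other 4298), 16 at least the 175 of pap1-D with tt4 (highest other 4105) and 7 at least the 31 of the combined lines (highest other 1369). These splits move arrays between genotypes that differ by themselves, so a regrouped interaction can take up such a difference, and splits with far more calls than the real one point to that structure. They give no reference without change, and whether chance can account for these 3 counts stays open. A change along the listing could also give calls in the interactions with tt4, since the overexpressors are listed after Col-0 but before tt4. Such a change was not separated from an effect of CHS. For the pairs of genotypes there are only 10 splits, too few for a share under 0.05. The real split alone reached its own count, 1 of 10, in 9 pairs, and the highest other count was 1 for MYB12OX against Col-0 (150), pap1-D/tt4 against pap1-D (2824) and MYB12OX/tt4 against tt4 (28). It was 0 for pap1-D (1508), WOX1-1 (2504), WOX1-2 (3446) and tt4 (5449) against Col-0, MYB12OX/tt4 against MYB12OX (2603) and pap1-D/tt4 against tt4 (22). For WOX1-2 against WOX1-1, with a real count of 0, all 10 splits gave at least as many, at most 1.

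Among the comparisons with Col-0, the number of changed probe sets grew with the distance in the sample listing, from 150 at 3 positions to 1508, 2504, 3446 and 5449, but MYB12OX/tt4 against tt4 had 28 at 6 positions. A gradual change of the arrays along the listing could account for part of this: array 3 lay above array 1 on component 1 in 8 of 8 genotypes (permutation p = 2e-05), and the change within the 6 other genotypes, carried over the listing distance of each pair, was 1.39 ± 0.14 (SE) of the difference from Col-0 in tt4, 0.504 ± 0.160 in WOX1-2, 0.322 ± 0.138 in WOX1-1, 0.0425 ± 0.214 in pap1-D and 0.0423 ± 0.175 in MYB12OX. A batch shared by array number would give such a change too, and array 3 lay below array 1 on component 3 in 8 of 8 genotypes (permutation p = 0.00078), so these values, whose SE takes the genotypes as independent, leave a gradual change open in every comparison. In pap1-D and MYB12OX the share did not exceed its SE and so gave no sign of a gradual change. An array number effect running the other way could hide one there. A straight drift in everything that separates arrays 3 and 1 is not borne out, as tt4 minus Col-0 held only 2.17 ± 1.08 (jackknife SE) such steps in place of 21. Loss of CHS as the whole cause of this pattern does not account for WOX1-2, which has CHS and lay 30.7 above Col-0 on component 1. WOX1-2 carries overexpressed regulators that tt4 does not, so its place does not tell how far CHS loss accounts for the tt4 difference. That stays open because genotype and listing place coincide. RNA degradation does not account for the tt4 difference as far as 3' to 5' log2 ratios of control genes show it. Between tt4 and Col-0 these differed by -0.0281 for actin and -0.0140 for GAPDH, with pooled SDs within genotypes of 0.0732 and 0.109. Other measures of array quality were not tested as a cause. The cre control probe set read 18705, 17196 and 16561 on the tt4 arrays against 21212, 19153 and 20288 on those of Col-0.

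The rise of the anthocyanin genes in pap1-D is not explained by a gradual change along the listing, since 4 of 4 genes still passed with the listing place in the fit and DFR was at -0.17 in tt4, listed last. A rise that occurs only with CHS is ruled out, as 4 of 4 genes rose in pap1-D/tt4 against tt4. The rise in signal without CHS was 0.707 ± 0.058 (SE) of that with CHS as a mean over the genes, and UF3GT and AT5MAT fell in pap1-D/tt4 against pap1-D, by 0.60 and 0.57. A part that needs CHS stays open, because these genotypes also lie 12 positions apart in the listing. In addition, the mean signal of the pap1-D-linked probe set was lower in pap1-D/tt4 than in pap1-D, and whether this goes with the smaller rise was not tested. An effect of the overexpressed regulator remains a possible explanation, but PAP1 itself could not be checked by name.

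The glutathione transferase genes GSTU16, GSTU18, GSTU20 and GSTU27 were lower in tt4. Against Col-0 the family mean was -0.715 in tt4 and -0.393 in WOX1-2, a line with CHS (SE 0.0553 each). In listing order it was -0.0521 in MYB12OX, -0.166 in pap1-D, -0.318 in WOX1-1, -0.393 in WOX1-2, -0.542 in MYB12OX/tt4 and -0.690 in pap1-D/tt4. The fall in lines with CHS needs another cause, which may also act in tt4. Whether loss of CHS adds to it in tt4 stays open. A gradual change along the listing could account for the fall in WOX1-2 and in tt4. Array 3 lay below array 1 in 8 of 8 genotypes (permutation p = 0.014), and that change carried over 21 positions was -0.829. A batch shared by array number would lower array 3 in the same way, so this also stays open.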

How the results depend on the processing

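The fits with the listing place and without the arrays numbered 1 were chosen after the data had been seen. Of 244 named values, 218 passed in the fit reported, and the sign turned in none of them under any alternative fixed beforehand. With quantile normalization 237 stayed on their side of the threshold, 236 with array weights, 240 with the replicate block and 222 without the variance trend. On the contrasted genotypes alone 201 did so, with 42 no longer passing, and without the arrays numbered 1 it was 194, with 49 no longer passing. Leaving out each array in turn gave 1405 values on the same side, 313 no longer passing and 4 newly passing. Of the 218, 142 passed whichever array was left out, 76 lost the call without at least 1 array, and 15 moved by more than 1.5 times. The table holds no detection calls, so changes near background cannot be judged. Fewer arrays were used where an array was left out or only the contrasted genotypes were fitted. With the listing place as a covariate, errors grow with the listing distance. Whether other causes moved the counts was not tested.

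With the listing place as a covariate the counts were 24 for MYB12OX, 163 for pap1-D, 139 for WOX1-1, 103 for WOX1-2 and 84 for tt4 against Col-0, 45 for MYB12OX/tt4 against MYB12OX, 136 for pap1-D/tt4 against pap1-D, 144 and 80 for MYB12OX/tt4 and pap1-D/tt4 against tt4, 3 between the WOX lines, 20 for pap1-D with tt4 and 75 for MYB12OX with pap1-D. For MYB12OX with tt4 it was 34, with 0 of the 40 among them, and of the 175 for pap1-D with tt4 only 1 was among the 20. Of the 28 for MYB12OX/tt4 against tt4 only 3 were among the 144. In that fit 73 named values stayed on their side, 123 no longer passed and 48 turned sign, all with an adjusted p above 0.05. The trend is estimated only between arrays of a genotype, so errors grow with the listing distance. For AT4G14090 against Col-0 the SE was 0.35 in pap1-D, 0.48 in WOX1-1 and 0.63 in WOX1-2, but 0.16 in pap1-D without the covariate. An effect of array number would enter that trend too. A lost call or turned sign therefore does not show a change along the listing, and other causes were not tested. In WOX1-1 against Col-0: AT1G50040 -0.11, AT3G44450 0.27, BCAT4 0.36, AT2G31790 0.42. In WOX1-2 against Col-0: AT3G44450 0.59, AT1G72920 0.39, AT1G60590 1.01, ALDH2C4 -0.22, AT1G06000 0.069, AT1G22410 0.26, AT2G31790 0.51, UGT74B1 0.11. In tt4 against Col-0: COR27 -0.20, AT5G25440 -0.55, AT1G72060 -1.33, AT1G73600 1.03, AT1G60590 2.47, RCA 0.11, GH3.3 -3.24, UGT78D2 0.057, HCT 0.31, IAA29 -3.63, BCAT4 1.38, ALDH2C4 -0.22, AT1G06000 0.26, UGT78D1 0.76, AT1G22410 0.75, AT2G31790 1.29, COR15A 1.54, GI 0.12, the MYB12OX-linked probe set 0.036, a further unnamed probe set 0.15. In pap1-D/tt4 against pap1-D: AT5G19240 0.67, AT3G04640 0.82, ORA47 2.05, GH3.3 -1.82, ALDH2C4 -0.15, AT2G31790 0.73. In the interactions with tt4: AT1G72060 0.33 (MYB12OX) and 0.13 (pap1-D). In MYB12OX/tt4 against MYB12OX: GH3.3 -1.77, HCT 0.10, IAA29 -2.0, BCAT4 0.81, ALDH2C4 -0.19, AT1G06000 0.023, AT1G22410 0.37, AT2G31790 0.58.

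With the replicate number as a block the counts were 338 for MYB12OX against Col-0, 97 for MYB12OX/tt4 against tt4, 12 between the WOX lines, 184 for MYB12OX with tt4, 391 for pap1-D with tt4 and 55 for MYB12OX with pap1-D. The block changed no other count by more than 1.5 times, and at the preset correlation it gave 2 gene lists for MYB12OX/tt4 against MYB12OX and 1 for pap1-D with tt4. With an estimated correlation none of these was called: adjusted p = 0.176 for flavonol glycosylation and 0.0999 for auxin in MYB12OX/tt4 against MYB12OX, and 0.0859 for auxin in pap1-D with tt4. With the block and an estimated correlation the auxin list was called as lower in pap1-D/tt4 against tt4 (adjusted p = 0.00542, against 0.0727 without the block).

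Array weights gave 353 for MYB12OX against Col-0, 103 for MYB12OX/tt4 against tt4, 11 between the WOX lines, 137 for MYB12OX with tt4 and 67 for MYB12OX with pap1-D. For MYB12OX with tt4 the count was 21 without the offset, 11 without the filter, 63 with quantile normalization and 9 without the variance trend. For MYB12OX with pap1-D it was 18 without the filter and 18 without the variance trend. On the contrasted genotypes alone the counts were 82 and 935 for MYB12OX and pap1-D against Col-0, 1550 for pap1-D/tt4 against pap1-D, 9 and 14 for MYB12OX/tt4 and pap1-D/tt4 against tt4, 60 for pap1-D with tt4 and 17 for MYB12OX with pap1-D. Without the arrays numbered 1 they were 992 for pap1-D against Col-0, 12 for MYB12OX/tt4 against tt4, 2 between the WOX lines, 5 for MYB12OX with tt4 and 52 for MYB12OX with pap1-D.

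Leaving out each array in turn gave 34 to 211 for MYB12OX, 716 to 1378 for pap1-D and 1597 to 2308 for WOX1-1 against Col-0, 1571 to 2455 for MYB12OX/tt4 against MYB12OX, 1723 to 2664 for pap1-D/tt4 against pap1-D and 12 to 26 for MYB12OX/tt4 against tt4. For the interactions it gave 2 to 86 for MYB12OX with tt4, 53 to 254 for pap1-D with tt4 and 12 to 67 for MYB12OX with pap1-D. The counts of WOX1-2 (2482 to 3121) and tt4 (4499 to 5040) against Col-0 stayed within 1.5 times.

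With an estimated correlation camera called 0 gene lists in tt4 against Col-0 (2 at the preset), 0 in MYB12OX/tt4 against MYB12OX and in pap1-D/tt4 against pap1-D (1 each at the preset), and 1 in pap1-D/tt4 against tt4 (3 at the preset). Fry called 3, 2 and 2 lists in tt4 against Col-0, MYB12OX/tt4 against MYB12OX and pap1-D/tt4 against tt4. Quantile normalization gave 0 lists in MYB12OX/tt4 against MYB12OX.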

Other observations

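The gene families, the plastid set, the anther markers and the unnamed probe sets here were chosen after the data had been seen, as were all tests of the hypothesis below except the step size.

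Genes of the GSTU family, glutathione transferases, fell in plants without CHS. In tt4 against Col-0, GSTU20 fell by 1.37 ± 0.20 (SE), GSTU18 by 0.80 ± 0.08, GSTU16 by 0.67 ± 0.08 and GSTU27 by 0.50 ± 0.09, while GSTU26 was at -0.24 ± 0.15. The family was called as lower by camera (adjusted p = 0.0465 with an estimated correlation), also in MYB12OX/tt4 against MYB12OX (adjusted p = 0.0251) and in pap1-D/tt4 against pap1-D (adjusted p = 0.018). Its mean against Col-0 was also lower in lines with CHS, at -0.166 in pap1-D, -0.318 in WOX1-1 and -0.393 in WOX1-2, while MYB12OX was at -0.0521. All 5 tested CRR genes, for editing and assembly of the plastid NDH complex, fell in tt4, led by CRR41 (-1.21 ± 0.18) and CRR21 (-0.83 ± 0.09), and the family was called at the preset correlation (adjusted p = 0.00739; adjusted p = 0.0535 with an estimated correlation). The CRR mean was also lower in lines with CHS, at -0.355 in WOX1-1 and -0.510 in WOX1-2, where 4 of the 5 fell (adjusted p = 0.0341 at the preset correlation; adjusted p = 0.132 with an estimated correlation). Of 69 tested genes of the plastid chromosome, 42 fell in tt4 (adjusted p = 2.04e-11 at the preset correlation; adjusted p = 0.509 with an estimated correlation). Quantile normalization left the GSTU call (adjusted p = 0.0428 with an estimated correlation), and gave 4 of 5 lower CRR genes in tt4, and 33 lower and 1 higher gene of the plastid chromosome.

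Besides DFR, AT4G14090, UF3GT, AT5MAT and UGT78D2, the 12 probe sets raised by pap1-D with and without CHS were unnamed. Among the strongest, 1 rose by 4.68 in pap1-D and 4.32 in pap1-D/tt4, and a probe set that 2 genes share by 3.45 and 2.83. The tt4 minus Col-0 and MYB12OX/tt4 minus MYB12OX differences, measured on separate arrays, correlated at 0.807 across probe sets, and tt4 minus Col-0 and pap1-D/tt4 minus pap1-D at 0.741. These differences also run the same way along the listing, over 21, 12 and 12 positions, so their correlation does not separate CHS loss from a change along it. The differences of MYB12OX from Col-0 and of MYB12OX/tt4 from tt4 correlated at 0.104, and those of pap1-D from Col-0 and pap1-D/tt4 from tt4 at 0.360. Along the listing the MYB12OX differences run over 3 and -6 positions and those of pap1-D over 6 and -3. A change along the listing would therefore lower these correlations, so they do not show how far a regulator's effect depends on CHS. Of 4 tested anther markers, ROXY2 fell in pap1-D against Col-0 (-1.33 ± 0.25) and rose in pap1-D/tt4 against pap1-D (1.22 ± 0.25), and ATA27 rose in MYB12OX/tt4 against MYB12OX (1.67 ± 0.51), while EMS1 and BPEp passed in no comparison. ROXY2 and ATA27 had already been named among the largest changes, so the list adds no separate support. ATA27 averaged 2.31 in MYB12OX and 116 ± 86.3 (SD) in MYB12OX/tt4. It did not pass in tt4 against Col-0 (adjusted p = 0.286) or pap1-D/tt4 against pap1-D (adjusted p = 0.875).

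A hypothesis is that plants were harvested, or arrays processed, in the order of the listing, so that a gradual change such as time of day adds to the genotype differences. The test was whether arrays of 1 genotype change along their numbers as the genotypes do: the permutation p was 2e-05, and the share carried over the listing distance was 1.39 ± 0.14 for tt4, 0.504 ± 0.160 for WOX1-2, 0.322 ± 0.138 for WOX1-1, 0.0425 ± 0.214 for pap1-D and 0.0423 ± 0.175 for MYB12OX against Col-0. It was 1.18 ± 0.25 for MYB12OX/tt4 against MYB12OX, 1.2 ± 0.27 for pap1-D/tt4 against pap1-D, 1.76 ± 0.37 for MYB12OX/tt4 against tt4, 0.392 ± 0.216 for pap1-D/tt4 against tt4 and 2.91 ± 0.63 for WOX1-2 against WOX1-1. Shares well above 1 cannot be a part of a difference, which limits how the others can be read. Simulated data gave a share of 0.955 where 1 was put in and -0.000436 where 0 was put in. Within a genotype, number and listing place run together, so a batch shared by array number would give the same change, and it would add no difference between genotypes. Array 3 lay below array 1 on component 3 in 8 of 8 genotypes (permutation p = 0.00078), and tt4 minus Col-0 held only 2.17 steps of the whole change between arrays 3 and 1. Harvest and processing times are not given in the sources used here, so the hypothesis stays open.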
